A study of Homo sapiens with 4 samples.

How the data were processed

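RNA was measured by sequencing in 4 libraries of TOV21G, an established human cell line from an ovarian clear cell carcinoma. The groups are control cells given no drugs, cells given thiostrepton at 1 µM, cells given GSK458 at 0.1 µM, and cells given both drugs at these doses, with 48 h of drug treatment per the labels. Each group has 1 library, so no difference below has a replicate check, no standard deviation or p-value is given, and every comparison describes these libraries. RNA was extracted with a Qiagen column kit and libraries were made with the TruSeq stranded mRNA kit, which selects polyadenylated RNA, per the labels' protocols.

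The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with 26255 gene symbols, each on 1 row. The submitters' processing notes name the hg19 genome build, TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1, without saying which step each was used for. Whether strand was used in counting, and which annotation, is not given in the sources used here, so antisense genes and genes with near-identical copies are uncertain. No coordinates are printed because the reference at hand is of another build. The deposited FPKM summed to 543975 in the control library, 551529 with thiostrepton, 588892 with GSK458 and 576582 with both drugs. Among the 11555 genes at 1 FPKM or more in all 4 libraries, the median log2 deviation of each library from the gene means lay between -0.006 and 0.011, so the libraries appear to have been scaled to one another before deposit.

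FPKM does not give the number of reads. Low values lie on steps, as whole fragments would give. For genes above 0 and under 0.05 FPKM in both libraries, the ratio to the control value was divided by its most frequent value, the common step. For thiostrepton, GSK458 and both drugs, 84.5%, 83.6% and 83.0% of these then matched a ratio of whole numbers up to 4 within 1%. From the common step, the number of fragments per unit of FPKM relative to the control library was 0.936 with thiostrepton, 1.09 with GSK458 and 0.948 with both drugs. These are ratios of sequencing depth only if no scaling between libraries was applied. Absolute depth is unknown, and no counting interval is given. A gene listed at 0 can be a failed estimate, because 1 gene used by every cell, H3F3A, lay near 0 in 2 libraries.

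Values were analysed as deposited, as log2(FPKM + 1), for the 12812 genes with at least 1 FPKM in at least 1 library. A log2 difference is on this scale, which understates the change of low genes. Ratios printed beside it are ratios of the deposited FPKM. Genes were counted at a log2 difference of 1 or more in size, called 2-fold here. The groups form a 2 × 2 design, so the non-additive part of the combination was computed per gene as combination minus thiostrepton minus GSK458 plus control. The effect of each drug was also compared between both backgrounds, in pairs of differences that share no library. Correlations are across genes, which are not independent replicates. As a yardstick for a single difference, the robust spread of the non-additive part over genes divided by the square root of 2 gave 0.28. This holds any interaction of the drugs as well as noise, so it can overstate the noise. The robust spread of combination minus GSK458 was 0.169.

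For 34 gene lists with 946 members (915 distinct genes), the median difference of the measured members was given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A median is called outside the random range when it lies outside the middle 95% of those lists. This is a description, since random lists ignore that genes of a pathway vary together. For 30 lists with at least 3 measured members this was possible. If genes varied independently, chance would put 1.5 of the 30 outside in each comparison. Genes of a list can vary together, so more can lie outside without a drug effect. The value of 1.5 is therefore no chance level for these data.

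Genes were named by a rule. Ranking took genes with at least 5 FPKM in at least 1 of the libraries compared, without rows naming several genes, small RNA genes, Y-linked genes and XIST. Named were the 10 highest and 10 lowest differences from control for each treatment, the 5 highest and lowest for the combination against each single drug, the 5 genes per direction with the largest smaller difference over both backgrounds for each drug, and the 5 highest and lowest non-additive terms. Up to 4 members with the largest difference of a list described, and FOXM1, PIK3CA and MTOR, were added. A few genes that the rule selects are not reported here. Up to 5 genes per direction beyond all 3 other libraries in the combination were named after their values were seen, without the minimum of 5 FPKM. The comparisons, gene lists, the rest of the naming rule and the alternative settings not named otherwise below were fixed before the data were examined.

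Alternatives were pseudocounts of 0.1 and 0.01, no filter on low values, a filter of 5 FPKM, scaling by median ratio, to equal sums (TPM) or by upper quartile, a threshold of 1.5-fold, and random lists not matched on expression. Chosen after seeing the data were the removal of trends with transcript GC content and length, and a restriction to protein-coding genes that also drops the rows left out of naming, both from GENCODE 29 transcripts, which covered 98.0% of the 12812 genes. With no replicates, an alternative was taken to leave a value in place when a count stayed within 1.5 times, a list median moved by less than the distance from the middle to the edge of its random range, a gene moved by less than 0.28, or a correlation moved by less than 0.1. The steps were tested on simulated libraries for GSK458 minus control with 12446 genes. Normal noise had an SD of 0.198 per library, from the spread of the non-additive part, which also holds any interaction of the drugs. All 50 genes at 8-fold in either direction were counted, 45 of 50 at 2.83-fold higher and 47 of 50 at 2.83-fold lower, and 1 of 12246 unchanged genes was. Real noise at low values can have longer tails, so the last count says little about the real counts. Of 100 unshifted lists of 25 genes 3 lay outside the random range, and all 100 lists shifted by 0.5 lay above it. The simulated noise was independent between genes, and many medians reported below were smaller in size than 0.5. The check on lists therefore says little about those medians. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.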

Results

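The study measured gene expression in TOV21G cells, a cell line from ovarian clear cell carcinoma, after 48 h with thiostrepton at 1 µM, GSK458 at 0.1 µM or both, beside cells given no drugs. Thiostrepton is a thiopeptide antibiotic that the series names as an inhibitor of FOXM1, a transcription factor of cell division genes. GSK458 inhibits both PI3K and mTOR, kinases of growth factor and nutrient signalling. Each group was 1 library. Between 12138 and 12249 genes reached 1 FPKM per library, and between 9846 and 10072 symbols were listed at 0. Small RNA genes took 0.091% of the summed FPKM in the control library, 0.132% with thiostrepton, 0.139% with GSK458 and 0.279% with both drugs. Few markers of other cell types reached 1 FPKM in any library. They were 2 of 10 fibroblast genes (COL1A1 at 2.65 FPKM and COL1A2 at 1.45 FPKM in control cells), 1 of 10 endothelial genes (ESAM, 0.474 FPKM), 1 of 13 leukocyte genes (CD68, 0.782 FPKM) and 2 of 8 mesothelial genes (MSLN, 4.30 FPKM, and BNC1, 1.42 FPKM).

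The first comparison asked what the FOXM1 inhibitor did alone. FOXM1 mRNA was 19.98 FPKM in control cells and 16.9 FPKM with thiostrepton, a log2 difference of -0.23. None of the 45 genes of the list of FOXM1 and mitotic genes was 2-fold apart. Their median difference was 0.08, at percentile 90.6 of matched random lists, and the members farthest from 0 were CENPF (-0.51), BUB1 (0.49), PTTG1 (0.48) and KIF2C (0.37). Genes of DNA replication and S phase were lower with thiostrepton, with a median of -0.51, 44 of 47 below 0 and 3 of them 2-fold lower. The replication factor GINS2 went from 17.6 to 7.07 FPKM and UHRF1, which maintains DNA methylation, from 15.9 to 7.45 FPKM.

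All 31 measured proteasome subunits lay below the control value with thiostrepton (median -0.29, none 2-fold), with PSMC3 at -0.79 and PSMC4 at -0.65. Glycolysis genes had a median of -0.33, with 20 of 24 below 0, among them PGAM1 (-0.86) and LDHA (-0.73). The heat shock list had a median of -0.17, with 17 of 21 below 0, HSPA8 at -0.84, HSP90AA1 at -0.82 and CRYAB the other way at 0.66. The list of MYC and ribosome biogenesis genes had -0.18, with 21 of 33 below 0, although MYC itself was 0.88 higher, and mitochondrial ribosomal protein genes had -0.15, with 22 of 37 below 0. Of 5 measured metallothionein genes, 3 were below 0 and 2 above 0, with a median of -0.94. MT1E, MT1X and MT1F were lower by log2 differences from -1.04 to -0.94, 1 of them 2-fold. Each of these medians lay below its random range.

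NF-kB and cytokine genes were higher with thiostrepton, with a median of 0.42 and 18 of 21 above 0. Of the 27 genes listed, 4 are also in another list. CCL20, a chemokine, went from 2.59 to 10.1 FPKM, NFKB2 from 33.9 to 63.7 FPKM and BIRC3 from 4.35 to 8.68 FPKM. Genes induced by ERK signalling had a median of 0.34, with 3 of 22 at 2-fold, the phosphatase gene DUSP5 (10.8 to 42.8 FPKM), EGR1 (3.38 to 11.6 FPKM) and PHLDA1 (14.4 to 40.2 FPKM). The ATF4 and amino acid response list had 0.22, with 31 of 43 above 0, GDF15 at 1.35, DDIT3 at 0.97, ASNS at 0.95 and ATF5 the other way at -0.87. FOXO targets and receptor feedback genes (0.21, TXNIP at 1.26), fatty acid synthesis genes (0.21, 11 of 17 above 0, FADS2 at -0.80), mesenchymal and matrix genes (0.20, 20 of 28 above 0, CYR61 at 1.20), cytosolic ribosomal protein genes (0.15, 51 of 58 above 0) and NRF2 target genes (0.14, 20 of 28 above 0) also lay above their random ranges. The NRF2 median lay within the range of random lists not matched on expression.

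The largest increases of single genes with thiostrepton were SNHG25 (listed at 0 in control and 40.9 FPKM with the drug, an uncertain value with no ratio), RMRP (1.93 to 18.5 FPKM), TFPI2, a protease inhibitor typical of clear cell carcinoma (32.0 to 201 FPKM), FAM229A (2.21 on the log2 scale), LOC101929224 (0.404 to 5.03 FPKM), DUSP5, SAT1, which acetylates polyamines (134 to 485 FPKM), CCL20, GATSL3 (1.62) and ICAM5 (1.62). Among the largest decreases were NUDT4P2 (-2.74), HNRNPM (104 to 27.2 FPKM), TCTA (-1.67), SFPQ (91.5 to 29.7 FPKM), STS (-1.55), NCOA5 (-1.54), CDC37L1-AS1 (-1.48), TMEM37 (-1.40) and the kinase gene SGK1 (20.5 to 7.19 FPKM). HNRNPM and SFPQ encode RNA-binding proteins of splicing. NUDT4P2 is a pseudogene at 0.0027 FPKM in this library, and RMRP is made by RNA polymerase III and largely lacks the poly(A) tail that the kit selects, so both values are uncertain. In all, 105 genes were at least 2-fold higher and 107 lower, of which 56 and 66 were protein-coding. With a pseudocount of 0.1 the counts were 289 and 285.

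**Figure D1:**
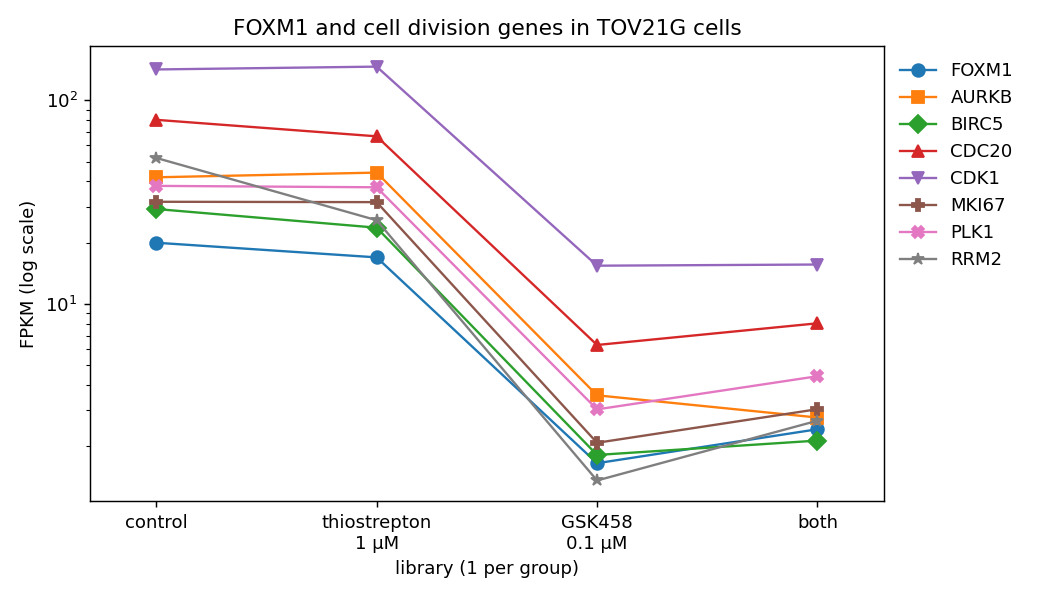
FPKM on a log axis of FOXM1 and 7 cell division genes in the 4 libraries, 1 point per library, with lines joining the points of a gene. FOXM1 stood at 19.98 and 16.9 FPKM without GSK458 and at 1.65 and 2.43 FPKM with it.

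The next comparison asked what the PI3K and mTOR inhibitor did alone. FOXM1 was 12.1-fold lower with GSK458, at 1.65 FPKM, and genes of cell division were lower as a group. Of the 45 FOXM1 and mitotic genes, all lay below control and 42 were at least 2-fold lower, with a median of -2.48. CDC20, which activates the anaphase-promoting complex, went from 80.1 to 6.29 FPKM, the proliferation marker MKI67 from 31.7 to 2.08 FPKM, BIRC5 (survivin) from 29.2 to 1.81 FPKM and the mitotic kinase gene PBK from 26.2 to 1.62 FPKM. Of the 47 replication and S phase genes, 40 were at least 2-fold lower (median -1.78). RRM2, a subunit of ribonucleotide reductase, was 38.3-fold lower, and UHRF1 (-3.23), CDC6 (-2.81) and TK1 (-2.65) followed. In the homologous recombination and Fanconi list 15 of 26 were 2-fold lower (median -1.14), led by RAD54L (-2.50), RAD51AP1 (-2.34), EXO1 (-2.33) and FANCI (-2.32).

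Metabolic genes were lower with GSK458. Glycolysis genes had a median of -0.65, with 10 of 24 at least 2-fold lower, among them PGAM1 (506 to 162 FPKM), HK2 (6.78 to 1.70 FPKM) and TPI1 (1184 to 412 FPKM). Sterol synthesis and uptake genes had -0.57, with 24 of 25 below 0 and 4 at 2-fold, among them ACAT2 (-1.80) and INSIG1 (-1.05). Fatty acid synthesis genes had -0.28, with SCD (-2.08), FADS2 (-1.54), SREBF1 (-1.42) and ELOVL6 (-1.10) 2-fold lower. The medians were -0.46 for proteasome subunits (30 of 31 below 0), -0.45 for nuclear genes of oxidative phosphorylation (40 of 43 below 0), -0.40 for mitochondrial ribosomal protein genes and -0.29 for endoplasmic reticulum chaperone genes, where CALR (-1.70) and SDF2L1 (-1.55) were lowest. The ATF4 list had -0.18 with members on both sides, as DDIT4 was at -1.93 and PHGDH, of serine synthesis, at -1.91 while GDF15 was at 1.58. These medians lay below their random ranges. Reference (housekeeping) genes had a median of -0.25, with 14 of 19 below 0, at percentile 3.6 of matched random lists and 1.59 of unmatched lists, so within the first range and below the second.

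All 58 cytosolic ribosomal protein genes were higher with GSK458 (median 0.53, none 2-fold). RPS27 went from 3398 to 6370 FPKM. These genes have many processed pseudogenes, which FPKM can share reads with. The ERK list had a median of 0.50 (DUSP5 at 1.46, MYC at 0.95), and FOXO targets and receptor feedback genes had 0.43, with 5 of 33 at least 2-fold higher. Among the latter, YPEL3 went from 9.26 to 46.2 FPKM, PIK3IP1, a negative regulator of PI3K, from 4.93 to 15.3 FPKM, the insulin receptor substrate gene IRS2 from 4.98 to 14.5 FPKM and GABARAPL1 from 118 to 298 FPKM. Mesenchymal and matrix genes (0.37, CTGF at 1.68) and clear cell carcinoma associated genes (0.32, TFPI2 at 1.74) also lay above their random ranges.

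GPX3, a secreted glutathione peroxidase, was 73.2-fold higher with GSK458, at 155 FPKM against 2.12 FPKM in control. Other genes with the largest increases were SHISA2 (3.15), LOC100505817 (2.55), the sterol hydroxylase gene CYP27A1 (4.26 to 29.3 FPKM), the signalling ligand gene SHH (0.994 to 10.3 FPKM), RBFOX3 (2.39), RMRP (2.37, uncertain as above) and EPB41L4A-AS1 (11.7 to 58.9 FPKM). SNHG25 and H3F3A also ranked among them, both uncertain. H3F3A, a histone H3.3 gene, was at 0.0099 FPKM in control, 0.012 FPKM with thiostrepton, 9.47 FPKM with GSK458 and 21.2 FPKM with both drugs. As every dividing cell uses this gene and it has near-identical copies, its low values are treated as estimates that failed. The remaining genes with the largest decreases were PLK1 (-3.27), FAM64A (-3.26), AURKB (-3.23) and UBE2C (-3.23). PIK3CA was at 10.2 FPKM in control and 12.4 FPKM with GSK458, and MTOR at 13.6 and 9.83 FPKM. The counts were 299 genes at least 2-fold higher and 490 lower, 232 and 452 of them protein-coding. With a pseudocount of 0.1 they were 582 and 717.

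Cells given both drugs also had lower cell division genes than control cells, in a comparison that shares the control library with those above. FOXM1 was 8.23-fold lower than in control, at 2.43 FPKM. The FOXM1 and mitotic list had a median of -2.42 with 42 of 45 genes 2-fold lower, S phase genes -1.72 (41 of 47), homologous recombination and Fanconi genes -1.13 (19 of 26), glycolysis genes -0.70 (8 of 24) and sterol genes -0.60 (5 of 25). Medians below the random range were also those of oxidative phosphorylation (-0.48), endoplasmic reticulum chaperone (-0.47), proteasome (-0.45), fatty acid synthesis (-0.40), mitochondrial ribosomal protein (-0.40), mitochondrial stress (-0.33) and ATF4 genes (-0.31). NF-kB and cytokine genes were lower than in control with both drugs, at -0.39, with 4 of 21 at least 2-fold lower. Cytosolic ribosomal protein genes (0.49, 58 of 58 above 0), mesenchymal genes (0.39), ERK genes (0.36), FOXO targets (0.36) and clear cell carcinoma associated genes (0.19) lay above their ranges, the last of them only with random lists matched on expression.

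The genes with the largest increases over control with both drugs were SNHG25 (uncertain, as above), GPX3 (67.9-fold), H3F3A, CYP27A1 (37.2 FPKM), SHISA2 (2.79), LOC100505817 (2.39), YPEL3 (52.9 FPKM), the steroid dehydrogenase gene HSD17B2 (1.87 to 13.6 FPKM), the nuclear RNA NEAT1 (28.6 to 133 FPKM) and EPB41L4A-AS1 (2.12). The largest decreases were RRM2 (19.5-fold lower), AURKB (15.1-fold), PBK (16.1-fold), DLGAP5 (15.6-fold), BIRC5 (13.7-fold), UBE2C (10.2-fold), CDC20 (9.97-fold), KIF2C (13.0-fold), SPC24 (12.8-fold) and CDK1 (9.07-fold). The counts were 313 genes higher and 505 lower, with 200 and 471 protein-coding, and 623 and 723 with a pseudocount of 0.1.

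**Figure D2:**
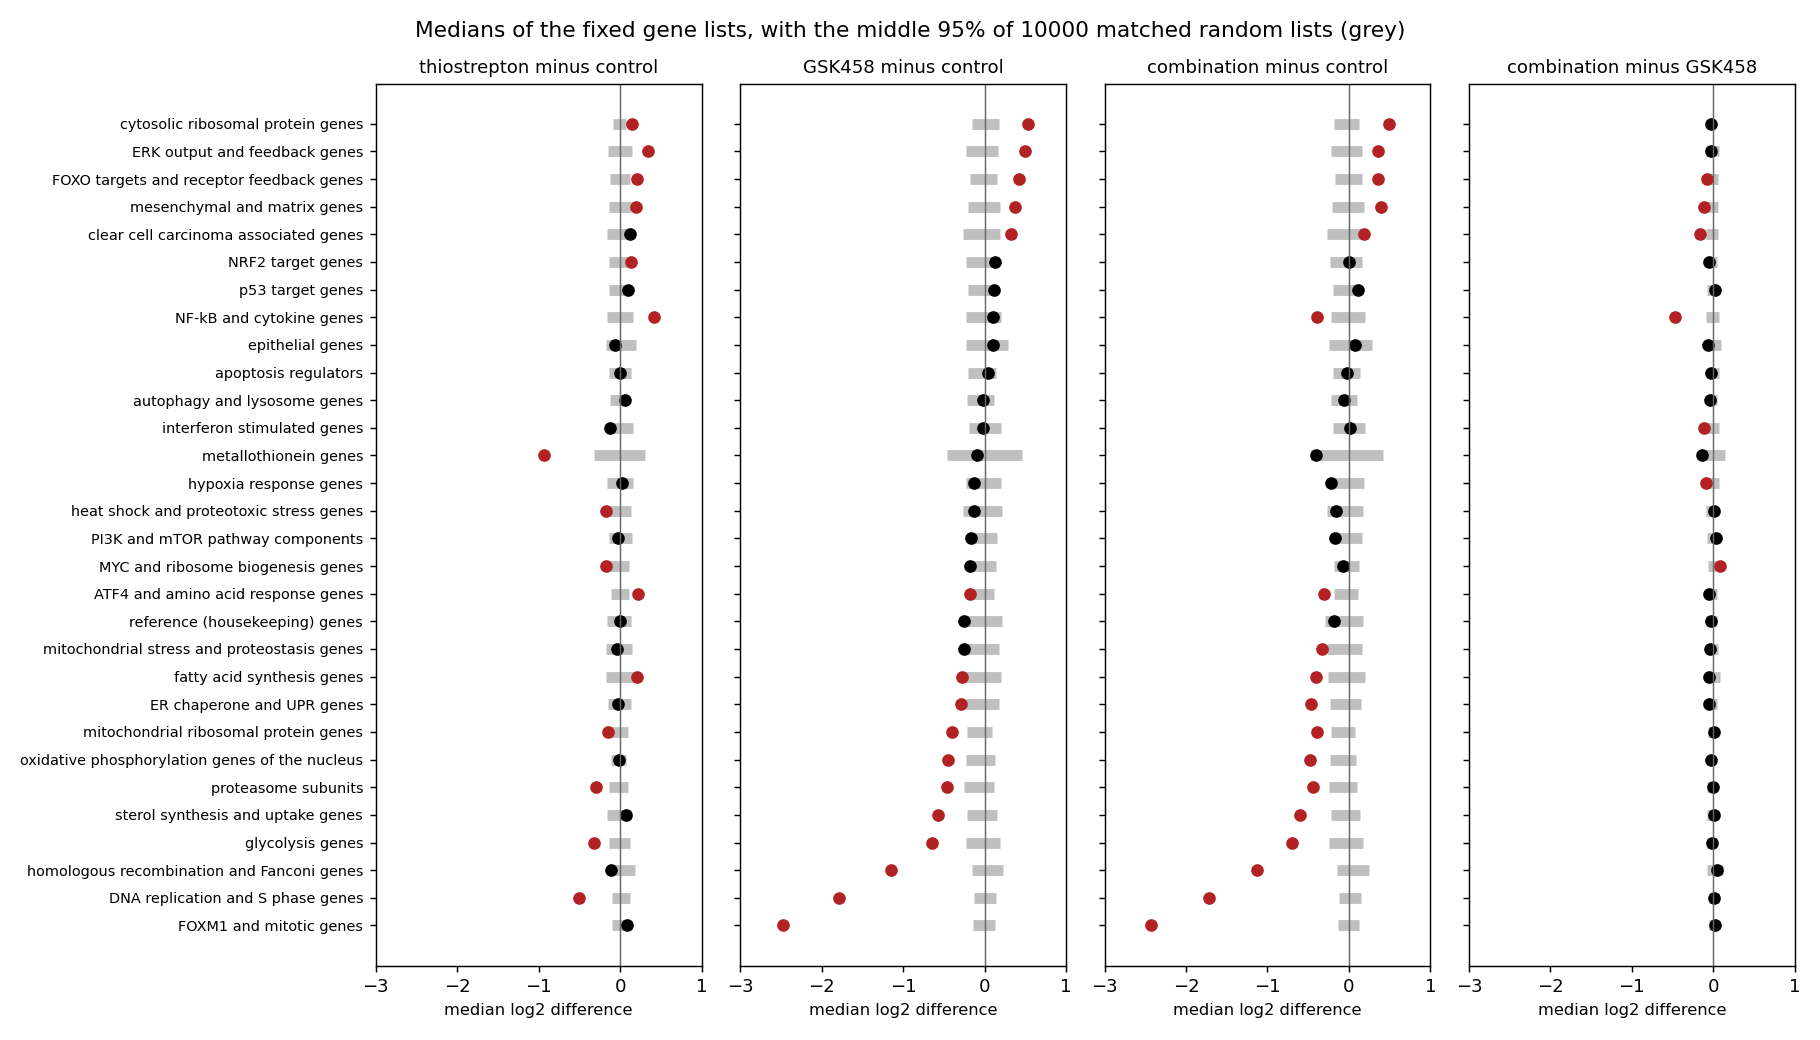
Median log2 difference of each fixed gene list with at least 3 measured members (points, red where outside the random range) in 4 comparisons, with the middle 95% of 10000 matched random lists as grey bars. The mitotic list lies at -2.48 with GSK458 and at -2.42 with both drugs, and the NF-kB list at 0.42 with thiostrepton and at -0.47 for both drugs against GSK458.

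The question of a combined effect rests on the combination against each single drug. Against thiostrepton alone, cells given both drugs had lower cell division genes, with a median of -2.50 for the mitotic list (42 of 45) and -1.29 for the S phase list (30 of 47). Homologous recombination genes had -1.09, sterol genes -0.79 (8 of 25), NF-kB genes -0.56 (6 of 21), oxidative phosphorylation genes -0.47, ATF4 genes -0.43 (9 of 43), fatty acid synthesis and glycolysis genes -0.40 each, endoplasmic reticulum chaperone genes -0.36, reference genes -0.29, mitochondrial stress genes -0.27 and mitochondrial ribosomal protein genes -0.25. Cytosolic ribosomal protein genes (0.37) and FOXO targets (0.27) lay above their ranges. GPX3 (69.7-fold higher), H3F3A, NUDT4P2, FAM133DP and CYP27A1 (9.46-fold higher) had the largest increases. NUDT4P2 and FAM133DP, a further pseudogene, were near 0 with thiostrepton alone. AURKB (-3.58), DLGAP5 (-3.57), KIF2C (-3.51), PBK (-3.40) and TOP2A (-3.22) had the largest decreases. The counts were 335 higher and 560 lower, 237 and 517 protein-coding, and 696 and 841 with a pseudocount of 0.1.

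Against GSK458 alone, adding thiostrepton moved few genes. The mitotic list had a median of 0.03, with 30 of 45 above 0. The S phase list had 0.01, with 25 of 47 above 0. Both medians lay within their random ranges. No gene of either list was 2-fold apart on the log2(FPKM + 1) scale, which understates the change of low genes. By deposited FPKM, UHRF1 of the S phase list was 2.22-fold higher with both drugs than with GSK458 (0.811 to 1.80 FPKM). FOXM1 was 1.65 FPKM with GSK458 and 2.43 FPKM with both drugs. NF-kB and cytokine genes stood apart, with all 21 lower in the combination (median -0.47, 1 at 2-fold). CCL20 went from 2.59 to 0.595 FPKM, CCL2 from 5.82 to 2.64 FPKM, SOD2 from 357 to 210 FPKM and CXCL3 from 2.78 to 1.28 FPKM. Smaller medians below the random range were those of clear cell carcinoma associated (-0.16), mesenchymal (-0.11), interferon stimulated (-0.11), hypoxia response (-0.09) and FOXO target genes (-0.07), and the MYC and ribosome biogenesis list lay above it (0.08, UBTF at 0.46). The genes with the largest decreases were TXNIP, a thioredoxin-binding protein gene (347 to 150 FPKM), MGARP (5.06 to 1.67 FPKM), the elongation factor gene EEF1A2 (78.5 to 35.7 FPKM), FBXO2 (-1.03) and PCAT6 (-1.02). The largest increases were FAM133DP (1.10), H3F3A, PVRIG2P (1.01), LINC00342 (1.00) and BCYRN1 (0.96), of which only H3F3A is protein-coding. The counts were 58 genes higher and 28 lower, but 36 and 17 of these were small RNA, readthrough or other rows left out of naming, and 9 and 8 were protein-coding after those were removed. With a pseudocount of 0.1 the counts were 133 and 109.

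Beyond all 3 other libraries, the combination was at least 2-fold higher for 28 genes and lower for 6, and for 46 and 41 with a pseudocount of 0.1. Restricted to protein-coding genes outside the rows left out of naming, these were 1 (H3F3A) and 2 (CCL20 and MGARP). The low values of H3F3A are treated above as failed estimates. CCL20 and MGARP were low in the combination, at 0.595 and 1.67 FPKM. The other rows named were PIK3IP1-AS1, LOC101928402, RBM12B-AS1 and PVRIG2P, all higher and at most 5.65 FPKM.

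The effect of each drug was then compared between cells with and without the other drug, in differences sharing no library. For GSK458 the differences went together, with Pearson r 0.587 and Spearman rho 0.549 across genes. At least 2-fold higher in both backgrounds were 95 genes and lower were 299, where independent lists would share 7.82 and 21.4. Another 11 genes went opposite ways, 7 of them rows left out of naming. For genes going opposite ways with either drug, no number for independent lists was computed. GPX3, LOC100505817, CYP27A1 and SHISA2 led the higher genes beside H3F3A, and PBK, AURKB, CDK1, KIF20A and UBE2C the lower. For thiostrepton they did not, with r -0.117 and rho -0.224. At least 2-fold the same way in both backgrounds were 6 higher and 4 lower genes, against 0.48 and 0.23 for independent lists, and 9 of these 10 were rows left out of naming. Opposite ways went 15 genes, of which 3 were higher without GSK458 and lower with it, and 12 lower and then higher, and 9 of these 15 were likewise rows left out of naming. Among protein-coding genes outside those rows r was -0.269 with 0 genes the same way in both, and with a pseudocount of 0.1 there were 20 higher and 13 lower in both. Ranked by the smaller of both differences, the higher genes were LOC100190986 (0.84 and 0.80), SNHG25, LOC100505915 (0.93 and 0.63), GTF2IRD2 (0.60 and 0.66), which has near-identical copies, and ZDHHC8P1 (0.57 and 0.84). The lower genes were PRSS56 (-0.95 and -0.53), RELL2 (-0.48 and -0.49), TYMP (-0.47 and -0.66), FGB, a fibrinogen chain (-0.68 and -0.47), and MMP7 (-0.46 and -0.48).

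**Figure D3:**
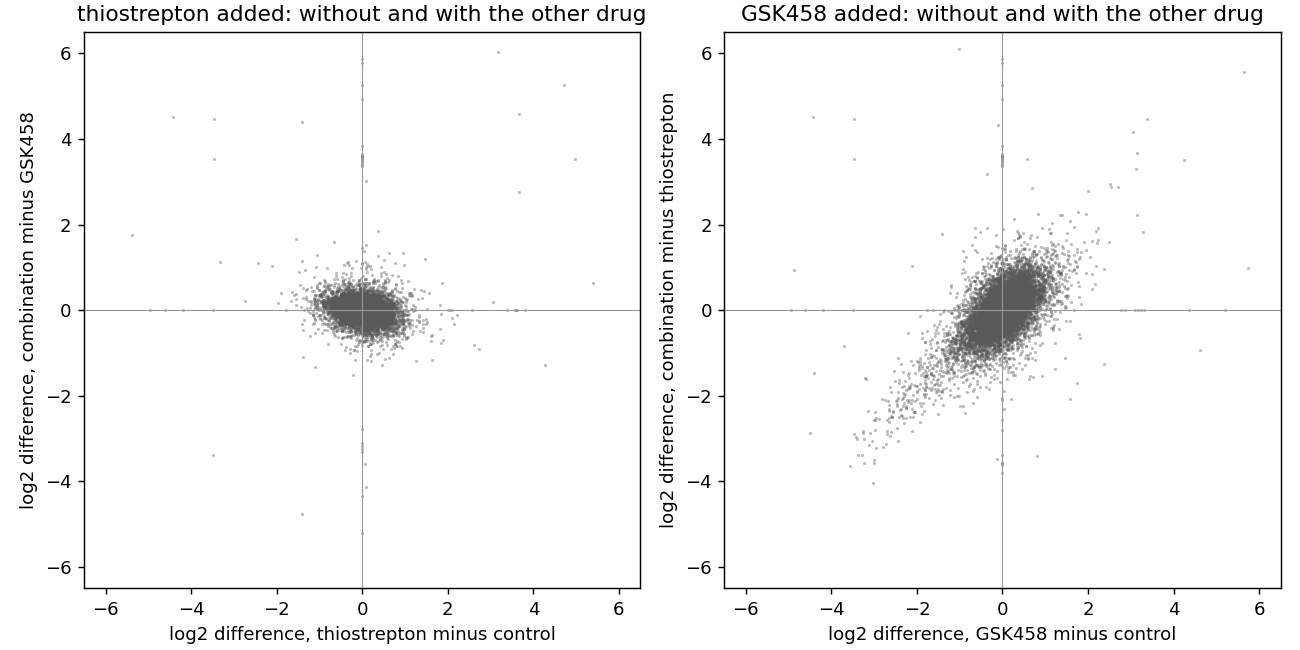
Each point is a gene, with its log2 difference on adding thiostrepton (left) or GSK458 (right) to untreated cells on the x axis and to cells with the other drug on the y axis. The 12812 genes gave r -0.117 for thiostrepton and 0.587 for GSK458.

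The non-additive part of the combination had a robust spread of 0.396 over genes, with 261 genes at 1 or above and 277 at -1 or below (179 and 208 protein-coding). The mitotic list was at 0.02, within its random range. NF-kB genes had -0.84, with all 21 below 0 and 8 at -1 or below. ERK genes (-0.44), mesenchymal genes (-0.40), FOXO targets (-0.32), clear cell carcinoma associated genes (-0.31), ATF4 genes (-0.27), hypoxia genes (-0.24) and cytosolic ribosomal protein genes (-0.19) were also below their ranges. Metallothionein genes (0.60), S phase genes (0.54, 43 of 47 above 0), heat shock genes (0.30), glycolysis genes (0.28), proteasome subunits (0.25, 30 of 31 above 0), MYC and ribosome biogenesis genes (0.22) and homologous recombination genes (0.21) were above. The lowest terms were those of SNHG25, which rests on the 0 listed in control, RMRP (-3.64, uncertain as above), TFPI2 (-3.44), CCL20 (-2.80) and SAT1 (-2.62). The highest were those of FAM133DP (3.55), NUDT4P2 (2.96), CDC37L1-AS1 (2.36), HNRNPM (2.30) and DEFB109P1, a pseudogene listed at 0 with thiostrepton. With a pseudocount of 0.1 the counts were 537 and 554.

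Lists of p53 targets, apoptosis regulators, autophagy and lysosome genes, epithelial genes, and PI3K and mTOR pathway components stayed within their random ranges in all 5 comparisons and in the non-additive part. Their medians in combination minus control were 0.11, -0.02, -0.06, 0.08 and -0.18. Single members moved more, as PIK3R3, a regulatory subunit of PI3K, was 23.2 FPKM in control, 8.89 FPKM with thiostrepton, 5.33 FPKM with GSK458 and 7.92 FPKM with both drugs, and the apoptosis gene BMF was 7.24 FPKM in control and 22.8 FPKM with GSK458. Across the 30 lists, the medians outside the random range were 8 above and 7 below for thiostrepton, 5 and 11 for GSK458, 5 and 13 for both drugs against control, 2 and 13 against thiostrepton, and 1 and 6 against GSK458. No list median outside its range changed sign under another scaling.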

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

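Of the tests below, those of random lists, of single cultures, of scaling and of the S phase list were chosen after the results were seen, while the tests with GC content and length trends removed were set before their results were seen. The differences between backgrounds in the next paragraph were not tested against replicates, since each background has 1 library per group.

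NF-kB and cytokine genes went opposite ways when thiostrepton was added to untreated cells (median 0.42) and to cells with GSK458 (-0.47). The same held for FOXO targets and receptor feedback genes (0.209 and -0.072), for mesenchymal and matrix genes (0.20 and -0.11) and, in the other direction, for MYC and ribosome biogenesis genes (-0.178 and 0.084). The medians of the differences between backgrounds were -0.84, -0.32, -0.40 and 0.22, each outside its random range, which describes these libraries. These lists were picked for medians outside the range with opposite signs in both backgrounds. The last values follow largely from that choice and add no support. Among named genes, CCL20 was at 1.63 without and -1.17 with GSK458, TXNIP at 1.26 and -1.20, and FAM133DP, a pseudogene, at -2.45 and 1.10. For GSK458 added to untreated cells and to cells with thiostrepton, TFPI2 was at 1.74 and -1.70, SAT1 at 1.24 and -1.38, DUSP5 at 1.46 and -1.12, and RMRP, an uncertain value, at 2.37 and -1.27. These genes were picked for opposite signs at differences of 1 or more in size. They came from genes named for extreme values in these same libraries, some of them in thiostrepton minus control or the non-additive part. Their opposite signs follow in part from that choice and add no support.

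Beyond named genes there was a shift the other way, small for genes higher with thiostrepton. Of the 105 genes at least 2-fold higher with thiostrepton alone, 60 were below 0 when thiostrepton was added to GSK458. Only 3 of the 105 were at least 2-fold lower there, and 6 were at least 2-fold higher. Their median as a set of 105 was -0.103, where matched random lists gave -0.033 to 0.059. Noise that is independent between genes would leave the median inside that range. With GC content and length trends removed from combination minus GSK458, the median was -0.07 over 98 genes, still below the range of -0.035 to 0.055. That argues against such a bias of this difference as the whole cause. The genes were still chosen by the uncorrected thiostrepton difference. Combination minus GSK458 also had little trend to remove, with Spearman rho -0.004 for GC content and 0.073 for length. An accidental difference between single cultures or library preparations cannot be told apart from an effect of the drugs, because each group has 1 library.

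The 107 genes at least 2-fold lower with thiostrepton alone had a median of 0.205 when it was added to GSK458, with 77 above 0 and random lists at -0.032 to 0.056. That argues against noise independent between genes. The median was 0.197 over 100 genes with GC content and length trends removed from combination minus GSK458, again with genes chosen before the removal. A difference between single cultures or preparations stays open for these genes too, as 1 library per group gives no spread to set against it. A response to thiostrepton that depends on PI3K and mTOR activity may be an alternative, and it was not tested.

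The lower level of mitotic genes in both libraries with GSK458 was weighed too. Total composition or scaling of the libraries would move genes alike, but the median of the list was -2.478 with GSK458 where matched random lists gave -0.144 to 0.127. S phase genes were lower as well, with a median of -1.783 with GSK458, below the random range of -0.127 to 0.142. The decrease was thus not confined to the FOXM1 and mitotic list. The S phase median was already known when this test was chosen. The test cannot separate a loss of FOXM1 that also lowers S phase genes from other causes. No conclusion on FOXM1 as a cause is drawn from it. A general slowing of proliferation under GSK458 is a hypothesis that stays open and was not tested.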

How the results depend on the processing

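The restriction to protein-coding genes, which also drops the rows left out of naming, and the removal of GC content and length trends were chosen after seeing the data. No correlation, no list median outside its random range and no named gene at a difference of 1 or more changed direction under any alternative that kept it. The filter of 5 FPKM, the removal of GC content and length trends and the restriction to protein-coding genes dropped some of these values. Median ratio scaling, upper quartile scaling, no filter on low values and removal of GC content and length trends left the gene counts, correlations and mitotic list medians in place. Summing rows of a symbol changed nothing because each symbol has 1 row. In each pair below the count of higher genes comes first. For thiostrepton minus control the counts were 289 and 285 at a pseudocount of 0.1, 329 and 325 at 0.01, and 616 and 590 at a threshold of 1.5-fold, with 56 and 64 among protein-coding genes and 169 lower genes with TPM scaling. For GSK458 minus control they were 582 higher at 0.1, 619 and 747 at 0.01, and 1123 and 1341 at 1.5-fold. For combination minus control they were 623 higher at 0.1, 676 higher at 0.01, 1180 and 1310 at 1.5-fold, and 199 higher among protein-coding genes. For combination minus thiostrepton they were 696 and 841 at 0.1, 741 and 881 at 0.01, and 1307 and 1509 at 1.5-fold. For combination minus GSK458 they were 133 and 109 at 0.1, 150 and 144 at 0.01, 164 and 149 at 1.5-fold, 9 and 8 among protein-coding genes, and 35 higher with a filter of 5 FPKM. For the non-additive part they were 537 and 554 at 0.1, 581 and 604 at 0.01, 1061 and 1125 at 1.5-fold, 170 at 1 or above with a filter of 5 FPKM and 400 with TPM scaling. Genes moved by thiostrepton in both backgrounds numbered 20 and 13 at 0.1, 28 and 17 at 0.01, and 0 and 0 among protein-coding genes, where r was -0.269. Genes higher with GSK458 in both numbered 227 at 0.1 and 251 at 0.01, where r was 0.405. Genes beyond all 3 other libraries in the combination numbered 46 and 41 at 0.1, 51 and 59 at 0.01, and 1 and 2 among protein-coding genes, with 11 lower under TPM scaling. The mitotic list median was -2.98, -3.01 and -2.81 for GSK458 minus control at 0.1, 0.01 and TPM scaling, -2.78, -2.80 and -2.74 for combination minus control, and -2.81, -2.88 and -2.71 for combination minus thiostrepton. Smaller pseudocounts and lower thresholds count more genes by construction, and the filters count fewer because fewer genes enter. TPM scaling raised all values while the pseudocount stayed at 1, so it also acts as a smaller pseudocount. How much of the TPM changes this accounts for was not tested. The median of all genes in GSK458 minus control went from -0.003 to -0.108 with TPM scaling, so changes under it are relative to that shift. In thiostrepton minus control that median was -0.012 with TPM scaling. TPM scaling changed the sign of 15 of 180 list medians, upper quartile scaling of 6 and median ratio scaling of 1, all of them within their random ranges. Of the other list medians and named genes, 127 values moved at a pseudocount of 0.1, 132 at 0.01, 60 with TPM scaling and 1 without a filter. Random lists not matched on expression were run only for list medians, where 6 of 180 changed side of the random range. NRF2 targets with thiostrepton and clear cell carcinoma associated genes with both drugs came to lie within it, and mitochondrial stress, reference and MYC genes with GSK458 and hypoxia genes with both drugs outside it. Absolute depth is unknown, so the precision of low genes cannot be given.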

Other observations

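The gene families here were chosen after the values were seen, and none was set against random lists. The 12 measured SRSF genes had a median of -0.45 with thiostrepton, with 9 below 0 and 4 at least 2-fold lower, -0.39 with GSK458 and -0.42 with both drugs. The 22 HNRNP genes had -0.24 with thiostrepton, with 18 below 0 and 1 at least 2-fold lower, -0.32 with GSK458 and -0.23 with both drugs. When thiostrepton was added to GSK458 the SRSF and HNRNP medians were 0.12, with 10 of 12 above 0, and 0.08, with 18 of 22 above 0. The small nucleolar RNA host genes (SNHG, 18 measured) had a median of 0.72 with GSK458 and of 0.25 with thiostrepton. With GSK458, 17 were above 0, 5 at least 2-fold higher and 1 at least 2-fold lower. The dual-specificity phosphatase genes (DUSP, 17 measured) were at 0.41 with GSK458 and 0.14 with thiostrepton, and at -0.14 for both drugs against GSK458. None of these medians changed sign under the 3 other scalings.

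Of all rows, 21 reached 20 FPKM in a library and lay under 0.1 FPKM in another. Of these, 19 were rows left out of naming, such as small RNA genes, and the remaining 2 were H3F3A and SNHG25.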
